A study of Homo sapiens with 30 samples.

How the data were processed

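The series holds 30 sample records of chromatin immunoprecipitation sequencing (ChIP-seq) in SUM159 cells, a mammary carcinoma line. Peak lists of 12 H3K27ac libraries were analysed, and the other 18 records (inputs and immunoprecipitations of p63 or p73 among them) were not analysed here. Groups were taken from the sample labels alone. The lists comprised 2 libraries each of the ITGB4-high and ITGB4-low sublines and 1 library each of 8 conditions of ITGB4-high cells. Nothing in the labels says that the paired libraries came from separate cultures, so their spread may be technical. Replicate numbers follow the order of the records and pair nothing by themselves. Date stamps in the records tie replicate 1 of both sorted groups to one date (20170203) and replicate 2 to another (20170504). The knockout series carried 20190626, apart from the p73 and dual add-back libraries with 20190711. The input of the library labelled p63 also carried 20190711, and that of the library labelled empty vector 20190626.

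Per the labels' protocols, sonicated nuclei were immunoprecipitated and libraries were made with a Swift Biosciences kit. Reads were aligned with Bowtie2 to hg19 and peaks were called with MACS 1.4, per the submitters' processing notes. The settings of the caller, the use of input libraries and any removal of duplicates are not given in the sources used here. The deposited lists give a chromosome, start, end and score per peak, 1 list per library, with no sign of pooling. The scale of the deposited score is not stated. Each list starts near 9 (lowest scores from 9.02 to 9.14) and the score was used only to rank, filter and describe peaks within a list. Read depth is unknown, so the number of peaks and the length they cover stand in for the precision of each list, and a region without a peak is a region not called, not a region shown to lack acetylation.

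Peaks on chromosome Y (6 to 47 per list) were left out. Overlapping peaks of the 12 lists on the autosomes and X were merged into 73069 regions with a median width of 926 bp. A region counted as called in a library when at least 1 bp of a peak overlapped it. Similarity between libraries was the Jaccard index in base pairs. A region was ITGB4-high-only when both ITGB4-high libraries called it and neither ITGB4-low library did, and ITGB4-low-only in the opposite case. Such regions are specific within each date pair by construction. Their number was set against the other ways to part the 4 libraries into 2 pairs. With 3 splits in all, no p under 0.05 was possible and none was given.

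Shares of these regions called in the knockout series carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only and treat regions as independent. Each share was also placed among 10000 random sets of regions matched on the number of sorted libraries that called them and on 10 bins of peak score. These sets were drawn from regions called in exactly 2 sorted libraries, 1 of each ITGB4 group, most of them of the same date. Regions lost or gained against the non-targeting control were counted with 1 library per condition, so these differences have no replicate check and no p-value across regions was computed. Regions lost from dKO and the library labelled empty vector were compared with 1000 draws of 2 unchanged libraries. The draws took the chance of missing a region, per bin of 10 equal-sized bins of score, from ITGB4-high replicate 1 against replicate 2, and in repeats from dKO against the library labelled empty vector or that labelled p63. Clusters were runs of regions at most 100 kb apart for pairs of libraries and 50 kb apart for other sets, each compared with 1000 random draws of as many regions.

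Regions named in the text followed a rule fixed before the data were examined. It took the 10 ITGB4-high-only and the 10 ITGB4-low-only regions with the highest lower score over the 2 libraries of their group. It also took the 10 regions with the highest score in the control among those called in neither dKO nor the library labelled empty vector. Clusters were chosen after their values were seen. Positions are 1-based on hg19, from the peak lists. The gene table at hand is of GRCh38.p14, another build, so regions were not assigned to genes. The planned tests of gene lists, of the p53-family motif and of peaks over exons of TP63 and TP73 were therefore not run. From that table only the chromosomes of TP63 and TP73 were used.

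Fixed before the data were seen were repeats with the 36003 top-scoring peaks of every list, a score of at least 100, coverage of at least 50% of a region, windows of 500 bp and leaving out each sorted library. Added afterwards were a score of at least 20, loss defined on dKO alone or on dKO and the library labelled p63, other pairs for the chance of a miss, and merging without the libraries labelled empty vector and p63 or without p73KO. The procedure was tested on simulated peak lists of 20000 regions for the ITGB4-high against ITGB4-low comparison. It recovered 100% of 200 planted regions in each direction, called 45 and 46 more that were not planted, and returned the shares with an error of at most 5.5 percentage points. Planted regions were always called in their own group and never in the other, so full recovery was set by the design. Other regions were missed at random, less often than between the real replicates and with no date effect. The simulation thus checks the code and gives no error rate for the real lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.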

Results

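H3K27ac, a histone mark of active promoters and enhancers, was profiled by ChIP-seq in SUM159 cells, a human triple-negative mammary carcinoma line. Cells had been separated by ITGB4 (integrin beta 4, CD104), a laminin receptor subunit of basal epithelial cells, into ITGB4-high and ITGB4-low sublines, with 2 libraries each. ITGB4-high cells were also profiled with a non-targeting guide (NT), after CRISPR knockout of p63 (p63KO), of p73 (p73KO) or of both (dKO). The dKO cells were profiled again with an empty vector (EV), a p63 cDNA, a p73 cDNA or both (dual). p63 and p73 are transcription factors of the p53 family. Each of these 8 conditions had 1 library. The title of the series ties the 2 factors to the quasi-mesenchymal state of cancer stem cells.

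The peak lists of ITGB4-high cells held 37107.5 ± 1533.7 peaks (SD, n = 2) over 30.9 ± 1.56 Mb. Those of ITGB4-low cells held 49819 ± 3615 peaks (SD, n = 2) over 45.0 ± 2.35 Mb. The 8 lists of the knockout series held 46772 to 55392 peaks over 62.1 to 68.8 Mb. Merged over the 12 libraries, the peaks formed 73069 regions, of which 13403 (18.3%) were called in every library and 17512 in a single one.

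The comparison of ITGB4-high with ITGB4-low cells asked which elements carry acetylation in one state and not in the other. ITGB4-low cells had more private acetylated regions than ITGB4-high cells, 3982 against 925. With equal numbers of top-scoring peaks from every list the counts were 2219 and 1303. Another 13859 regions were called in all 4 libraries. Most private regions were modest peaks: 91.5% of the ITGB4-high-only and 85.3% of the ITGB4-low-only regions lay under the median score of a list that called them. These counts grew when 1 library was left out, since fewer lists had to meet the definition. ITGB4-high-only regions numbered 3887 without high replicate 1, 2533 without high replicate 2, 1989 without low replicate 1 and 1991 without low replicate 2. The ITGB4-low-only counts were 6305, 5836, 10432 and 12884 in the same order.

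The highest-ranked ITGB4-high-only region, chromosome 1:3630841-3636033, scored 238.3 and 91.6 in the 2 ITGB4-high libraries. Scores are the authors' values per peak and are not on a scale shared between lists. It belonged to 4 such regions within 39.0 kb (chromosome 1:3597029-3636033). In that span ITGB4-high libraries called 12 and 4 of 13 regions and ITGB4-low libraries called 0. The next were chromosome 8:128672791-128676416 (scores 86.9 and 178.7), chromosome 7:16136282-16139370 (80.3 and 83.4), chromosome 10:105658807-105662398 (80.6 and 79.9) and chromosome 2:3667532-3669806 (83.7 and 76.2). Ranks 6 to 10 were chromosome 1:209988060-209991019, chromosome 3:193546713-193550814, chromosome 21:40274264-40277049, chromosome 2:20410228-20415291 and chromosome 22:37649761-37651221.

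ITGB4-low-only regions gathered in domains. The largest cluster held 19 of them on chromosome 21:39511992-39716747, followed by 16 on chromosome 15:32955175-33146726 and 14 on chromosome 2:38292549-38497728. The largest cluster of 1000 random draws held 12. In the chromosome 15 span, the ITGB4-low libraries called 22 and 23 of 29 regions and the ITGB4-high libraries called none. The highest-ranked single regions were chromosome 8:124641327-124648090 (scores 102.3 and 97.2), chromosome 15:33066393-33069504 (94.8 and 114.3), chromosome 13:114598002-114604872 (186.7 and 91.4), chromosome 10:106696202-106697416 (111.2 and 89.4) and chromosome 2:134413511-134416863 (100.4 and 88.2). Ranks 6 to 10 lay on chromosomes 13, 15, 5, 3 and 8. ITGB4-high-only regions formed clusters of at most 4, within the range of random draws (95% of draws up to 4, highest 6).

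The date of the libraries parted the sorted samples more than ITGB4 did. Regions called in both libraries of the first date and neither of the second numbered 4893, and the opposite set 3337. The total of 8230 exceeded the 4907 of the ITGB4 split, while the crossed split gave 220. With equal numbers of peaks the totals were 7683 by date, 3522 by ITGB4 and 215 crossed. Each ITGB4-high library was closest to the ITGB4-low library of its own date (Jaccard index 0.493 and 0.473), and the 2 ITGB4-high libraries overlapped less (0.341). The group difference was thus smaller than the spread between replicates, although every group-only region held within both dates.

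**Figure D1:**
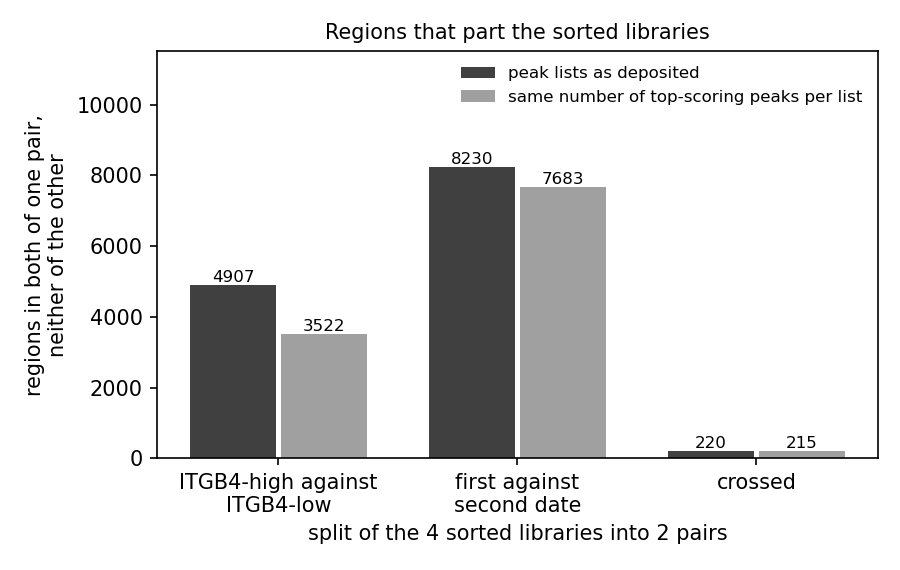
Number of regions (y axis) called in both libraries of one pair and neither of the other, for the 3 ways to part the 4 sorted libraries (x axis), summed over both directions. Dark bars are the lists as deposited and light bars the same number of top-scoring peaks per list; the date split (8230 and 7683) exceeded the ITGB4 split (4907 and 3522).

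Peaks give no test of the knockouts, but an added cDNA can leave short peaks over the exons of its gene. Exons were not located here, so runs of regions shared by a pair of libraries were sought over all chromosomes and set beside the chromosomes of TP63 and TP73. Among regions called in exactly 2 of the 12 libraries, the libraries labelled EV and dual shared 311. A run of 9 of these lay on chromosome 3:189525853-189612472 (86.6 kb), with peak scores of 21.6 to 161 in the library labelled EV and 29.5 to 109 in the dual library. The regions were 496 to 668 bp wide, and random draws gave at most 5. NT and dKO, neither with a cDNA, also shared a run above all their draws, 4 on chromosome X:143843652-143944508 against 3. Exceeding the draws is therefore not by itself a mark of an added cDNA. TP63 lies on chromosome 3, which holds 7.32% of all regions. The libraries labelled p63 and dual shared no run of more than 1 region. The p73 and dual libraries shared a run of 3 on chromosome 1:3638438-3649773, with up to 3 in random draws, and TP73 lies on chromosome 1. The short peaks thus went against the labels EV and p63, which are kept below as given.

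**Figure D2:**
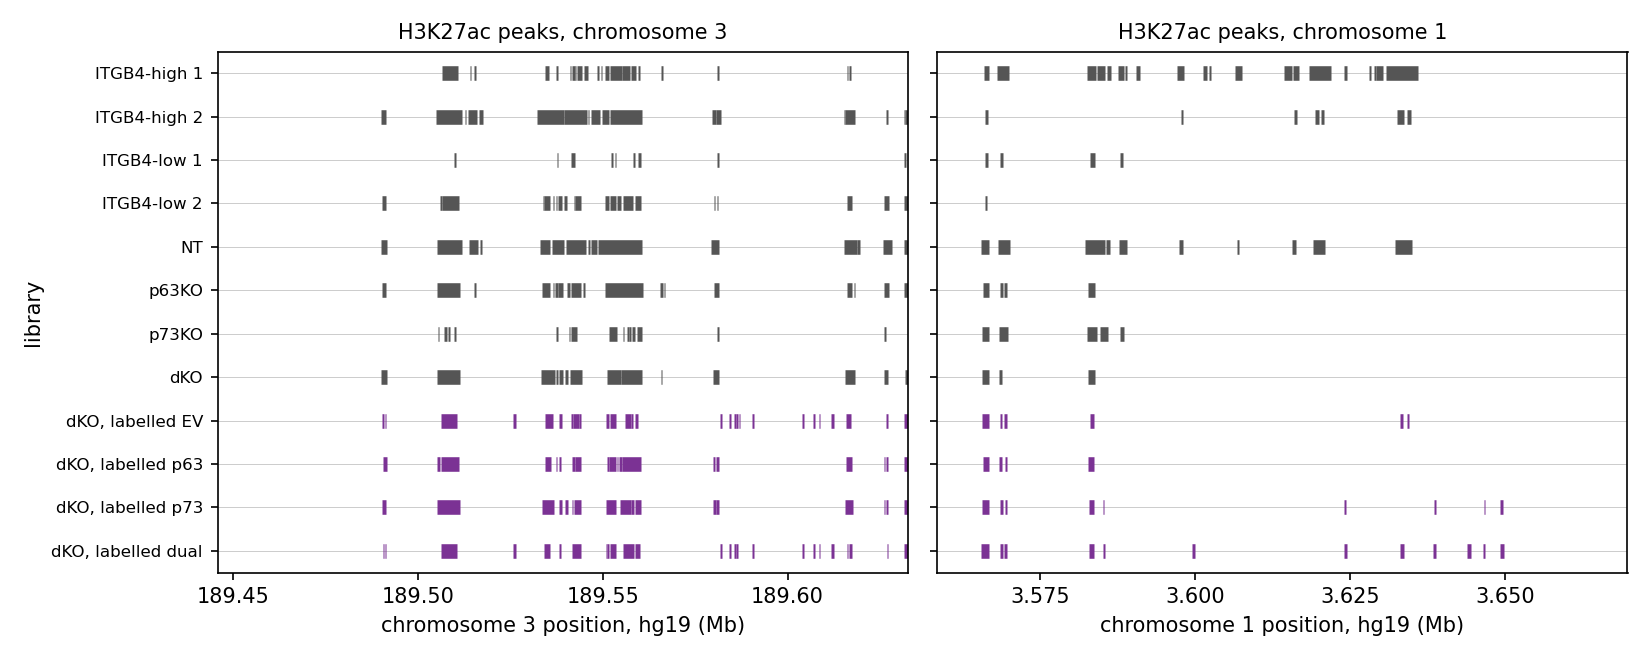
Peaks of each library (rows) along chromosome 3 and chromosome 1 (x axes, hg19 position in Mb); each block is a peak drawn to scale, purple for dKO cells with a vector and grey for the other libraries. On chromosome 3, the libraries labelled EV and dual share a run of 9 short regions that the library labelled p63 lacks, and on chromosome 1 the p73 and dual libraries share a run of 3.

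The ITGB4-high-only regions were then followed through the knockouts, which asks whether p63 and p73 are needed for acetylation there. In NT cells 79.9% of the 925 regions were called (95% interval 77.2 to 82.4). The single-knockout libraries called fewer of them, 25.1% in p63KO (22.3 to 28.0) and 25.5% in p73KO (22.7 to 28.5). In dKO 19.03% were called (16.5 to 21.7). The NT share lay at the 86.4 percentile of matched random sets (median 78.5%), whereas the p63KO, p73KO and dKO shares lay below all 10000 sets, whose medians were 81.4%, 68.0% and 77.4%. Matched regions were called in both ITGB4 groups, so the sets stand for regions not private to either group. Regions shared by the 4 sorted libraries were called at 98.5% to 99.6% in all 8 libraries of the series.

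Among the add-back libraries, the one labelled EV called 61.0% of the ITGB4-high-only regions (57.7 to 64.1) and the dual library 52.2% (48.9 to 55.5). The library labelled p63 called 16.6% (14.3 to 19.2) and the p73 library 16.2% (13.9 to 18.8), with intervals that overlapped that of dKO. All 4 lay below all 10000 matched sets, whose medians were 78.2% for the library labelled EV, 79.7% for dual, 75.2% for that labelled p63 and 77.4% for p73. Of 573 ITGB4-high-only regions called in NT and not in dKO, the library labelled EV called 67.9% (63.9 to 71.7) and the dual library 55.5% (51.3 to 59.6). The libraries labelled p63 and p73 called 3.66% (2.28 to 5.55) and 4.01% (2.56 to 5.96). Under the same choice, the library labelled EV called 57.1% of first-date-only and 65.8% of second-date-only regions, and the dual library 62.6% and 63.3%. The library labelled p63 called 37.7% and 23.6% of them, and the p73 library 37.4% and 41.2%. Against date-only regions, the ITGB4-high-only regions thus stood out by low shares in the libraries labelled p63 and p73, not by high shares in the dual library. Any direction read from the libraries labelled EV and p63 rests on the labels in doubt.

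All 10 top-ranked ITGB4-high-only regions were called in NT, in the library labelled EV and in the dual library. The p63KO library called 4 of them, p73KO 3, dKO 3, and the libraries labelled p63 and p73 2 each. Of the 10, 5 had a peak in these 3 libraries and in none of the other 5: those at chromosome 1:3630841-3636033, chromosome 8:128672791-128676416, chromosome 2:3667532-3669806, chromosome 1:209988060-209991019 and chromosome 21:40274264-40277049. In the first of these the peaks of the dual library (3633088-3633711) and of the library labelled EV (3633055-3633537 and 3634164-3634527) were short, against 3632342-3635009 in NT.

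Defined within one date only, regions of ITGB4-high and not of ITGB4-low cells were again called more often in NT, the library labelled EV and the dual library than in the other 5, whose order changed. For the first date NT called 67.2%, p63KO 43.6%, p73KO 39.4%, dKO 37.4%, the library labelled EV 54.3%, that labelled p63 35.9%, p73 36.6% and dual 52.2% of 3677 regions. For the second date the shares were 61.5%, 35.4%, 32.7%, 37.2%, 53.5%, 32.2%, 35.4% and 48.0% of 5093 regions. The dKO share depended on both ITGB4-low libraries: without low replicate 1 it was 52.1% and without low replicate 2 56.8%. Over the same omissions p63KO gave 61.4% and 59.4%, p73KO 63.2% and 44.5%, the library labelled p63 51.0% and 53.5%, and the p73 library 51.7% and 55.4%. The NT share was 51.0% without high replicate 1, the dual share was 34.7% without it and 33.9% without high replicate 2, and the share in the library labelled EV was 37.5% without high replicate 2. The p73KO share was 13.2% without high replicate 1. In every one of these settings NT, the library labelled EV and the dual library stayed above the other 5. Each of these sets contains all ITGB4-high-only regions by construction. The repeats are therefore not independent. In the regions added without high replicate 2, and in those added without low replicate 1, the order did not hold. There p73KO called more regions than the library labelled EV or the dual library, so the order rested on the shared ITGB4-high-only regions. In the regions added by the other sets the order held.

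**Figure D3:**
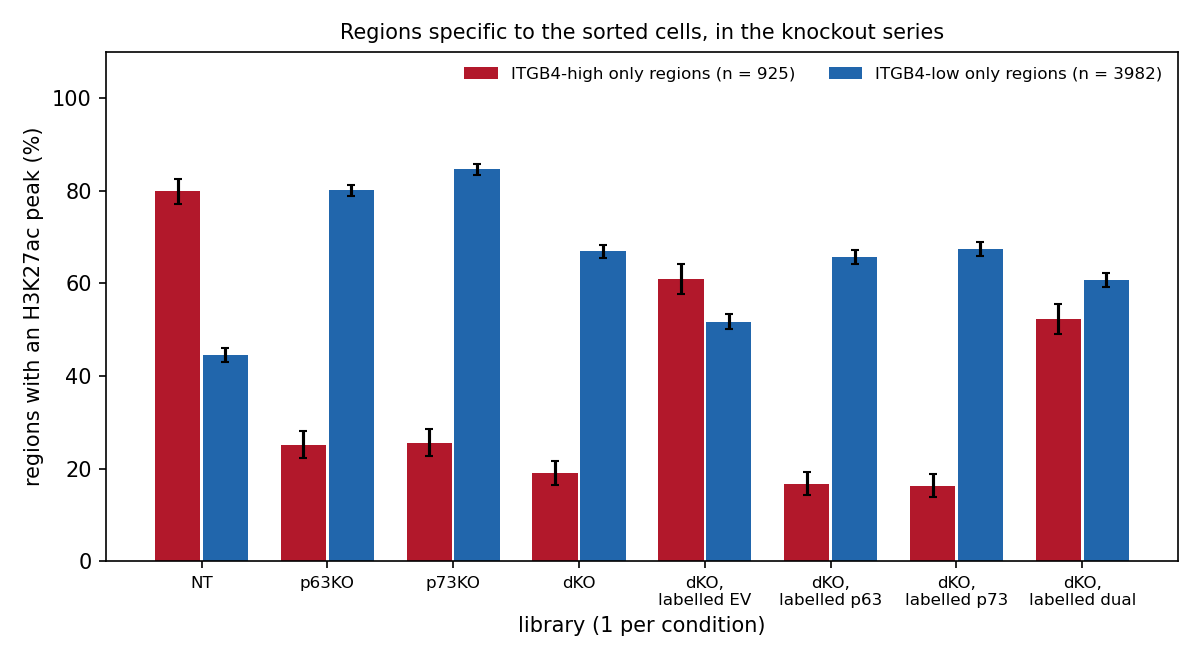
Percentage of ITGB4-high-only (red, 925) and ITGB4-low-only (blue, 3982) regions with a peak (y axis) in each of the 8 libraries of the knockout series (x axis); error bars are exact 95% binomial intervals, for counting error only. High-only regions were called at 79.9% in NT and 19.03% in dKO, and low-only regions at 44.5% and 66.9%.

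ITGB4-low-only regions moved the other way. NT cells called 44.5% of the 3982 regions (42.9 to 46.0), p63KO 80.04% (78.8 to 81.3), p73KO 84.6% (83.4 to 85.7) and dKO 66.9% (65.4 to 68.3). The library labelled EV called 51.7% (50.1 to 53.3), that labelled p63 65.7% (64.2 to 67.1), the p73 library 67.3% (65.8 to 68.8) and the dual library 60.7% (59.1 to 62.2). Only p73KO lay above its matched sets (median 69.3%). The other 7 lay below all of theirs, with medians of 80.4% for NT, 83.5% for p63KO and 79.9% for dKO, so the higher shares in p63KO and dKO hold against NT and not against matched regions. Of 1106 ITGB4-low-only regions called in dKO and not in NT, p63KO called 92.5% and p73KO 92.8%, against 49.0% and 36.8% of all regions called in dKO and not in NT. Their shares were also high in the opposite case, 79.4% and 88.8% of 214 ITGB4-low-only regions called in NT and not in dKO. Of the 1106, the libraries labelled p63 and p73 called 81.1% and 82.0%, the dual library 60.7% and the library labelled EV 43.6%. In the same order, these libraries called 54.3%, 58.9%, 39.9% and 35.5% of all regions called in dKO and not in NT. Of the 214 they called 38.8%, 48.6%, 58.9% and 47.2%. The p73KO library also called 96.5% of the first-date-only and 29.7% of the second-date-only regions, where the other 7 libraries called 80.7% to 93.0% and 69.7% to 83.8%. The matched sets were drawn largely from these date-only regions, so the 29.7% lowers the matched median of p73KO.

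Within one date, p63KO, p73KO and dKO again called more regions of ITGB4-low and not of ITGB4-high cells than NT, with smaller differences. These sets contain all ITGB4-low-only regions, so they are not independent of them. In the regions added to them, p63KO called more than NT for both dates. There dKO called fewer than NT for the first date, and p73KO slightly fewer for the second. For the first date (14880 regions) NT called 39.0%, p63KO 59.9%, p73KO 71.8%, dKO 43.4%, the library labelled EV 38.6%, that labelled p63 45.7%, p73 45.0% and dual 43.3%. For the second date (12833 regions) the shares were 42.1%, 61.7%, 54.1%, 61.6%, 48.8%, 55.9%, 59.5% and 53.02%, so that the library labelled EV lay above NT for the second date and not for the first. Without low replicate 2 the dKO share of low-only regions was 36.4% and the NT share 31.9%, a smaller gap than with both replicates. In the regions added by this omission dKO called fewer than NT. Without low replicate 1 the p73KO share was 44.0%, that of dKO 53.9% and that of NT 30.7%. In the regions added by that omission p73KO called fewer than NT, and dKO more. Without low replicate 2 the library labelled EV gave 30.8%, below NT, that labelled p63 39.0%, the p73 library 37.9% and the dual library 35.9%. Leaving out low replicate 1 gave 53.4% in p63KO and leaving out low replicate 2 gave 54.6%.

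Among the domains of ITGB4-low cells, the largest, on chromosome 21 (36 regions), had 2 regions called in NT, 7 in p63KO, 9 in p73KO and 5 in dKO, and 3 to 7 in the add-back libraries. The chromosome 2 span (34 regions) had 1 region called in NT, 20 in p63KO, 20 in p73KO and 17 in dKO. The libraries labelled EV and dual called 2 and 3 of them, and those labelled p63 and p73 called 11 and 9. In the chromosome 15 span NT called 4 of 29 regions, against 10 in p63KO and 11 each in p73KO and dKO. Of the 10 top-ranked regions of ITGB4-low cells, NT called 6, p63KO and p73KO 10 each, dKO 9 and the library labelled EV 8. The libraries labelled p63, p73 and dual called 9 each. The first, chromosome 8:124641327-124648090, had a peak in all 8 libraries. Chromosome 8:134171763-134178630 had a peak in each but NT and the library labelled EV. Chromosome 2:134413511-134416863 had one in p63KO and p73KO and in no other library of the series.

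Counted over all regions, each knockout lost and gained many calls against the 41323 of NT. p63KO lost 7488 (18.1%) and gained 8959, p73KO lost 9064 (21.9%) and gained 12699, and dKO lost 9578 (23.2%) and gained 8884. The library labelled EV lost 7415 (17.9%) and gained 5775. No replicates of 1 date were at hand for these conditions. Between the replicates of the sorted groups, which differ in date, 34.5% of the regions of ITGB4-high replicate 1 were not called in replicate 2, and 40.5% for ITGB4-low. Within the date stamp of the knockout series, 18.4% of the dKO regions were not called in the library labelled EV and 14.1% not in that labelled p63, against 17.9% to 23.2% of the NT regions lost above. With equal numbers of peaks the gains fell to 4219 in p63KO, 5284 in p73KO, 4166 in dKO and 2838 in the library labelled EV. The losses were then 6549, 7552, 8335 and 6280, so that p63KO and p73KO, which gained more than they lost with the lists as deposited, lost more than they gained.

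The dKO library and the one labelled EV, whose label is in doubt, lacked the same 5657 of the NT regions. Independent lists would share 1719, and 2 unchanged libraries drawn against the shared NT library lost a median of 5874 in common, with 14251 lost per library. That draw takes its misses from ITGB4-high libraries of different dates. With misses taken from dKO against the library labelled EV the draws lost 3542 in common, and against that labelled p63 2470, all of 1 date stamp. The cross-date draw lost more per library than dKO (9578) or the library labelled EV (7415) did, so it is no like comparison. The draws of 1 date stamp reached at most 3722 and 2627, both under 5657. They lost 7612 and 5833 per library, fewer than dKO, so no draw matched the losses and the excess has no exact size. Of the 10 with the highest NT score, chromosome 20:58630054-58632352 (193.0) and chromosome 2:154260136-154261213 (126.6) had no peak in any of the other 11 libraries. Chromosome 10:24543636-24546269 (177.4), chromosome 6:150592889-150594313 (121.1) and chromosome 20:35986157-35988236 (108.8) also had a peak in both ITGB4-high libraries, with none elsewhere. The ITGB4-low libraries called 1 and 0 of the 10.

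The add-back comparison asked how many lost regions return with each factor. Of the 5657, the library labelled p63 called 10.5% (9.71 to 11.3), the p73 library 9.12% (8.38 to 9.90) and the dual library 14.0% (13.1 to 14.9). In 20244 regions called in none of NT, dKO and the library labelled EV, the same libraries called 10.04%, 9.12% and 7.14%. The library labelled EV cannot call any of the 5657 by definition. The single knockouts called 24.7% (p63KO) and 34.6% (p73KO) of the 5657, against backgrounds of 19.5% and 42.6%. With loss defined on dKO and the library labelled p63 instead, 7877 regions, the library labelled EV called 35.7% (34.7 to 36.8), the dual library 30.9% (29.9 to 32.0) and the p73 library 10.6% (9.92 to 11.3). Their backgrounds were 10.5%, 9.68% and 7.53%. The single knockouts, which hold no add-back, called 25.8% (p63KO) and 34.2% (p73KO) of the 7877, against backgrounds of 17.0% and 40.1%. With loss defined on dKO alone, 9578 regions, the shares were 17.8% in the library labelled p63, 19.6% in the p73 library, 38.1% in the dual library and 40.9% in the library labelled EV. Here p63KO called 35.2% and p73KO 42.3%, so libraries without an add-back reached like shares, and no background was counted. At a score of at least 100 the dual share of regions lost in both was 35.6%. That cutoff keeps a larger part of some lists than of others. The upper quartile of the score was 144.9 in NT and 116.0 in the dual library. It was 90.3 in dKO, 97.9 in the library labelled EV, 86.1 in that labelled p63 and 85.8 in the p73 library.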

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

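The tests on these clusters, on the list length and on the date stamps were chosen after the values were seen. A signal outside the planned comparisons appeared as 9 regions called only in the libraries labelled empty vector and dual, in 1 run on chromosome 3 (189525853-189612472), and as 3 regions called only in the p73 and dual libraries, in 1 run on chromosome 1 (3638438-3649773). NT and the other 9 libraries called none of these 9 regions.

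The library labelled empty vector called 61.0% of the ITGB4-high-only regions against 19.03% in dKO, while the library labelled p63 called 16.6%. A longer peak list is argued against, since the list labelled empty vector was shorter than that of dKO by 2246 peaks and than that labelled p63 by 442. The date stamp of the H3K27ac libraries is argued against too. Those labelled empty vector and p63 share a stamp and differ by 44.3 percentage points, and the p73 and dual libraries share one and differ by 36. The inputs of the libraries labelled empty vector and p63 differ in stamp, however, and whether inputs entered the peak calls is not given. An exchange of the 2 libraries or of their labels needs short peaks on the chromosome of TP63 in the library labelled empty vector and none in that labelled p63. There were 9 against a run of at most 1, so an exchange is a candidate explanation; if it holds, the return of ITGB4-high-only regions may follow p63, alone or with p73, and not p73 alone. The effect of added p63 itself, as the biological side, stays untested until the identity of both libraries is settled.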

How the results depend on the processing

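The scores of at least 20, the loss defined on dKO alone or with p63, and the merging without doubted libraries were chosen after the data were seen. EV, p63, p73 and dual name the dKO libraries so labelled. In the 10 ways of calling and leaving out sorted libraries that gave all 8 shares, the lists as deposited among them, NT, EV and dual called a larger share of the ITGB4-high-only regions than p63KO, p73KO, dKO, p63 and p73. Without EV and p63, or without p73KO, this held for the libraries that were left. Sets with a sorted library left out contain all ITGB4-high-only regions of the main result, so those repeats are not independent. Among the regions added without high replicate 2 or without low replicate 1, p73KO called more than EV or dual. The gap was narrowest without high replicate 2 (33.9% against 29.8%), and at a score of at least 100 it rests on 11 regions (81.8% against 72.7%). Over 273 alternative values, 94 moved by less than the set limit (1.5 times for counts, the 95% interval for shares) and 179 by more. Merging without EV and p63, or without p73KO, moved no value past it. Windows of 500 bp count length and not regions, so their counts are larger by construction, and leaving out a library loosens the definition of a group-only region. The cause of the other moves was not tested. The counts come from no test, so no test with a replicate block was run; sets defined within each date stand in the report. The gene-list and motif alternatives were not run. Depth is unknown, which limits any statement that a region lacked acetylation.

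With equal numbers of top-scoring peaks, 2219 ITGB4-low-only regions were found. The share of high-only regions called was 71.8% in NT, 21.2% in p63KO, 22.3% in p73KO, 49.6% in EV and 41.4% in dual. The share of low-only regions called was 37.7% in NT, 66.1% in p63KO, 71.6% in p73KO, 50.9% in dKO, 38.7% in EV, 53.3% in p63, 52.6% in p73 and 47.3% in dual. Regions gained against NT numbered 4219 in p63KO, 5284 in p73KO, 4166 in dKO and 2838 in EV. The share of lost regions called again was 15.6% in dual.

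At a score of at least 100, 11 ITGB4-high-only regions and 138 ITGB4-low-only regions were found. Scores are not on a shared scale, and this cutoff kept a larger part of the NT, p63KO, p73KO and dual lists than of the dKO, EV, p63 and p73 lists. Losses, gains and returns at this cutoff may therefore reflect the scale of the lists. The share of high-only regions called was 72.7% in p63KO, 63.6% in p73KO, 54.5% in dKO, 81.8% in EV, 54.5% in p63, 45.5% in p73 and 90.9% in dual. The share of low-only regions called was 79.7% in NT, 93.5% in p63KO, 97.8% in p73KO, 89.9% in dKO, 79.7% in EV, 79.0% in p63, 81.9% in p73 and 89.9% in dual. Regions lost against NT numbered 2447 in p63KO, 1745 in p73KO, 5591 in dKO and 4243 in EV. Regions gained against NT numbered 1266 in p63KO, 3296 in p73KO, 802 in dKO and 412 in EV. A total of 3515 regions were lost in both dKO and EV. The share of lost regions called again was 8.31% in p63, 5.75% in p73 and 35.6% in dual.

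When at least 50% of a region had to be covered, 572 ITGB4-high-only regions were found. The share of high-only regions called was 71.2% in NT, 51.9% in EV and 46.3% in dual. The share of low-only regions called was 75.7% in p63KO, 81.7% in p73KO, 59.5% in dKO, 46.8% in EV, 60.6% in p63, 58.4% in p73 and 55.9% in dual. The share of lost regions called again was 11.6% in p63, 8.31% in p73 and 14.9% in dual.

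In 500 bp windows, 1790 ITGB4-high-only regions and 9924 ITGB4-low-only regions were found. The share of high-only regions called was 29.4% in p63KO, 21.4% in p63, 20% in p73 and 56.6% in dual. The share of low-only regions called was 50.8% in NT, 83.9% in p63KO, 88.4% in p73KO, 69.9% in dKO, 54.6% in EV, 70.7% in p63 and 63.8% in dual. Regions lost against NT numbered 24103 in p63KO, 36842 in p73KO, 33148 in dKO and 26116 in EV. Regions gained against NT numbered 28390 in p63KO, 36189 in p73KO, 27178 in dKO and 16769 in EV. A total of 19477 regions were lost in both dKO and EV. The share of lost regions called again was 15.3% in p63, 11.6% in p73 and 19.1% in dual.

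At a score of at least 20, the share of high-only regions called was 84.0% in NT, 30.3% in p63KO, 31.9% in p73KO, 25.7% in dKO, 68.4% in EV, 22.2% in p63, 23.8% in p73 and 59.7% in dual. The share of low-only regions called was 50.8% in NT, 81.3% in p63KO, 86.1% in p73KO, 70.9% in dKO, 56.4% in EV, 67.2% in p63 and 64.7% in dual. Regions gained against NT numbered 3842 in EV. The share of lost regions called again was 9.17% in p63 and 7.88% in p73.

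With loss defined on dKO alone, the share of lost regions called again was 17.8% in p63, 19.6% in p73 and 38.1% in dual. With loss defined on dKO and the p63 library, it was 10.6% in p73 and 30.9% in dual. The single knockouts p63KO and p73KO called 35.2% and 42.3% of the first of these sets, and 25.8% and 34.2% of the second.

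Leaving out each sorted library in turn, 1989 to 3887 ITGB4-high-only regions and 5836 to 12884 ITGB4-low-only regions were found. The share of high-only regions called was 51.0% to 89.3% in NT, 18.0% to 61.4% in p63KO, 13.2% to 63.2% in p73KO, 14.5% to 56.8% in dKO, 37.5% to 78.3% in EV, 14.2% to 53.5% in p63, 13.5% to 55.4% in p73 and 33.9% to 74.4% in dual. The share of low-only regions called was 30.7% to 62.1% in NT, 53.4% to 86.9% in p63KO, 44.0% to 90.0% in p73KO, 36.4% to 77.4% in dKO, 30.8% to 66.8% in EV, 39.0% to 76.4% in p63, 37.9% to 77.4% in p73 and 35.9% to 73.5% in dual.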

Other observations

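The tests of this part were chosen after the results were seen. Chromosome 12:114751765-114919083 held 20 regions, all called in NT and 19 in NT alone. None of the 4 sorted libraries and 1 region in p73KO had a peak there, although NT cells derive from the ITGB4-high subline. Random placement of regions called in 1 library is argued against by the largest cluster of 1000 draws, which held 11. Extra copies of the segment in the control cells stay open, as 0 regions of the span were called in any sorted library on which a gain could be measured. No biological explanation was tested.

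A domain of dKO cells lay on chromosome 3:151953441-152084239, where dKO called 25 of 30 regions and 11 in dKO alone among the 12 libraries, against 9 in the largest random cluster. NT called 7 of the 30, the libraries labelled p63 and p73 called 15 and 14, ITGB4-high replicate 2 called 13 and the dual library 10. A domain of p73KO cells lay on chromosome 11:34198819-34373077, with 35 of 37 regions called in p73KO, 16 of them there alone (largest random cluster 13), and 14 in NT. ITGB4-low replicate 1, p63KO and the library labelled p63 called 17 each, and the remaining libraries 6 to 14.

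More regions parted the 4 sorted libraries by date stamp than by ITGB4 group, 8230 against 4907. Lists of different length are argued against as the whole cause, since equal numbers of peaks left 7683 regions by date and 3522 by group. Regions close to the score at which the lists start are argued against only as the whole cause. Of the date-only regions 24.4% reached the median score of both lists that called them, against 13.6% of the group-only regions. The rest, 72.2% of the first-date-only and 80.7% of the second-date-only regions, lay under the median of a list that called them. Low scores can therefore still account for much of the date split. The score itself shifted with the date in both ITGB4 groups. Its median was 39.6 (high) and 36.8 (low) for the first date and 23.9 and 24.2 for the second. The upper quartiles were 92.7 and 74.9, then 35.3 and 37.5. Whether depth or enrichment differed by date was not tested. A difference between library batches or between cultures of the 2 dates stays open and untested, as the date is all that the records give.

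The span of 4 ITGB4-high-only regions on chromosome 1:3597029-3636033 lies next to the run of 3 regions shared by the p73 and dual libraries, which starts at 3638438. NT called 5 of its 13 regions, p63KO, p73KO, dKO and the library labelled p63 called 0, the libraries labelled empty vector and p73 called 1 each, and the dual library called 3. Of the peaks of the dual library, those at 3599436-3599926 and 3623960-3624492 were short, and the second was also present in the p73 library. The remaining call, at 3633088-3633711 in the top-ranked region, was short as well, and the p73 library had no peak there. In that region the library labelled empty vector also had short peaks, at 3633055-3633537 and 3634164-3634527.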
